A study of Gelatoporia subvermispora and Trametes versicolor with 24 samples.

How the data were processed

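RNA sequencing was analysed in 24 libraries, 12 from Gelatoporia subvermispora and 12 from Trametes versicolor. In each species agitated and static cultures with and without antioxidants made 4 groups of 3 libraries. Species, agitation, antioxidants and replicate number of each library were taken from its title in the labels. Per the labels' protocols, total RNA was extracted from frozen mycelium ground in liquid nitrogen and treated with DNase, and libraries were made with a stranded total RNA kit and sequenced on an Illumina NextSeq 550.

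The deposited values are raw read counts per gene, 1 table per library, not normalised. The submitters' processing notes name FastQC, Bowtie2, Bowtie and HTSeq, with no versions or roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Each table ends in HTSeq's summary lines for reads that were not counted. They were kept out of library sizes and tests. In G. subvermispora, 31.4 to 49.1% of the reads were left out for low mapping quality, 0.55 to 1.39% were not aligned, and 4.61 to 5.32% fell outside genes. In T. versicolor the corresponding ranges were 10.4 to 13.2%, 14.4 to 22.3% and 10.9 to 15.3%. Reads that could belong to more than 1 gene came to 0.21 to 0.27% and 0.37 to 0.98%. Reads that match several gene copies usually carry low mapping quality, so genes with near-identical copies are uncertain. Without a stated strand setting, overlapping and antisense genes are uncertain too.

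The tables list 12313 genes for G. subvermispora and 14570 for T. versicolor under running numbers, and the files do not pair these numbers with names. No reference annotation was used here. The 27 gene lists fixed before the data were examined, which included ligninolytic peroxidases, laccases, cytochromes P450, oxidant defence and aromatic ring breakdown, could therefore not be filled. Their set tests were not run and no list has a result. The rule for named genes, also fixed in advance, then took for each comparison the 2 largest rises and 2 largest falls among genes at adjusted p under 0.05, with a mean log2 CPM of at least 3 and with no overlap between the replicates of the compared groups. The condition on overlap was dropped for the difference between antioxidant effects.

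Each species was analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 10529 and 10505. Libraries were scaled by TMM, and all 12 libraries of a species entered a model of 4 group means, so that all comparisons share 1 estimate of the spread with 8 residual degrees of freedom. A robust quasi-likelihood fit (glmQLFit and glmQLFTest) gave p-values, adjusted by the Benjamini-Hochberg method over the genes of each of 5 comparisons. These were static against agitated without and with antioxidants, antioxidants against none in agitated and in static culture, and the difference between the 2 antioxidant effects. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change was derived from it and the F statistic. CPM values are counts divided by the TMM-scaled library size in the usual CPM unit, given as mean ± SD over n = 3 libraries. Principal components and correlations between libraries used log2 CPM with a prior count of 2. Counting error alone is small for genes with many reads, and the errors given reflect the spread between libraries. Some named genes had few reads in 1 group. In T. versicolor without antioxidants, gene10802 had 6 to 15 reads in agitated libraries and gene4441 had 6 to 16 in static ones. For such groups counting error is not small, an SD over 3 libraries can fall below it, and large fold changes start near the floor.

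Replicate numbers were checked for pairing by the correlation across genes of the libraries' deviations from their group means. In static G. subvermispora, with against without antioxidants, the 3 same-number pairs correlated at 0.363, 0.173 and 0.465 and the other pairs at -0.366 to 0.1. This does not establish pairing. In static T. versicolor, libraries with different numbers correlated as highly, at 0.453 (replicate 1 without and 2 with antioxidants) and 0.46 (replicate 2 without and 1 with). The match in G. subvermispora may therefore be a coincidence. It comes from the counts alone, since the labels do not say what a number stands for.

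No pair of replicates agreed within sampling noise: the chi-square statistic per degree of freedom of their counts lay between 2.99 and 145.55. The test was run on simulated counts drawn from the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold in each comparison. The changed genes were picked above a minimum mean CPM, so the shares found do not hold for weakly counted genes. Each gene varied independently, so libraries that stand apart as a whole were not simulated. In agitated cultures with and without antioxidants, it found 89 and 99 of them among 10462 simulated genes of G. subvermispora, with 9 false calls, and 69 and 99 among 10367 of T. versicolor, with 6 false calls. For static cultures with and without antioxidants it found 93 and 97 among 10463 genes of G. subvermispora, with 16 false calls, and 70 and 98 among 10375 of T. versicolor, with 11. For the difference between antioxidant effects it found 75 and 93 among 10463 genes in G. subvermispora, with 5 false calls, and 22 and 91 among 10383 in T. versicolor, with 3, so 2-fold differences of this kind were mostly missed in the second species.

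Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors and library totals as scalings, no low-count filter and a filter of 10 CPM in 3 libraries. They also included the replicate number as a block, a fit to only the 2 groups compared, DESeq2 1.42.0, limma-voom (limma 3.58.1), a minimum absolute log2 fold change of 1, and leaving out each library in turn. Added after seeing the data were limma-voom with library quality weights, T. versicolor without its 2 agitated replicate 1 libraries or without its 6 most abundant genes, G. subvermispora thinned to lower depths, and a replicate block in its static libraries only.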

Results

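RNA was sequenced from 2 white-rot fungi, wood-decaying basidiomycetes that break down lignin, the aromatic polymer of plant cell walls. Gelatoporia subvermispora and Trametes versicolor were grown at 28 °C in 25 mL of a defined Czapek-Dox medium with 15 mM cellobiose, the glucose disaccharide of cellulose. Flasks were either shaken at 220 rpm or left standing. Every culture received about 2 mM 4-hydroxybenzoate, a lignin-related aromatic acid, on day 10 for G. subvermispora and day 6 for T. versicolor. The antioxidants ascorbic acid (at 5 mM) and α-tocopherol (at 1 mM) had been added shortly before to some of the shaken and some of the standing flasks. Mycelium was collected 24 h after the 4-hydroxybenzoate, on day 11 or day 7. Each species thus had 4 groups of 3 libraries, agitated or static and with or without antioxidants, which makes 24 libraries. All cultures were induced, so no comparison addresses the effect of 4-hydroxybenzoate itself. The species also differed in culture age, and they were analysed separately because their gene sets are separate. The labels do not say whether the 3 replicates of a group came from separate flasks, so the p-values measure the spread between these samples only.

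The number of reads assigned to genes set the precision of each library. In G. subvermispora it was 25707667, 22027586 and 20673893 in agitated cultures without antioxidants and 17489642, 21773783 and 16696073 in agitated cultures with them. The static libraries held 7875324, 17939417 and 22838686 reads without antioxidants and 26653884, 23530945 and 17585100 with them. The T. versicolor libraries were shallower, with 6725806, 5621837 and 6116725 reads in agitated cultures without antioxidants and 6324260, 6283039 and 5993709 with them. In static T. versicolor the totals were 3431340, 5945365 and 5589354 without and 4995917, 4784617 and 5579448 with antioxidants. After removal of weakly counted genes, 10529 of 12313 genes were tested in G. subvermispora and 10505 of 14570 in T. versicolor. The biological coefficient of variation between replicates was 14.3% and 20.3%, respectively. Genes carry only running numbers in the deposited tables, with no names or products, and the numbers of the 2 species are unrelated. Genes are therefore given by number, and gene groups are defined by their response. Named genes come from the better-counted genes, with a mean log2 CPM of at least 3 and no overlap between the compared groups, and the largest rise or fall refers to these.

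Agitation separated the libraries of both species more than antioxidants did. The first principal component held 69.8% of the variance in G. subvermispora and 55.9% in T. versicolor, and in both it placed all 6 static libraries apart from all 6 agitated ones. In G. subvermispora the second component, 11.0% of the variance, parted agitated cultures with antioxidants from those without. In T. versicolor the second component, 12.6%, spread the agitated libraries without parting the antioxidant groups. Some libraries stood apart from their own group. Agitated antioxidant replicate 3 of G. subvermispora correlated across genes with replicates 1 and 2 at 0.972 to 0.975, against 0.995 between those 2. Agitated replicate 1 without antioxidants of T. versicolor correlated with its own group at 0.955 to 0.964 and agitated antioxidant replicate 1 at 0.957 to 0.959. Both correlated more highly with a library of the other antioxidant group, at 0.973 and 0.969. So did agitated replicates 2 and 3 without antioxidants, at 0.982 each. In G. subvermispora, static replicate 1 without antioxidants correlated with its own group at 0.985 to 0.987. Its correlation with static antioxidant replicate 2 was higher, at 0.99.

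**Figure D1:**
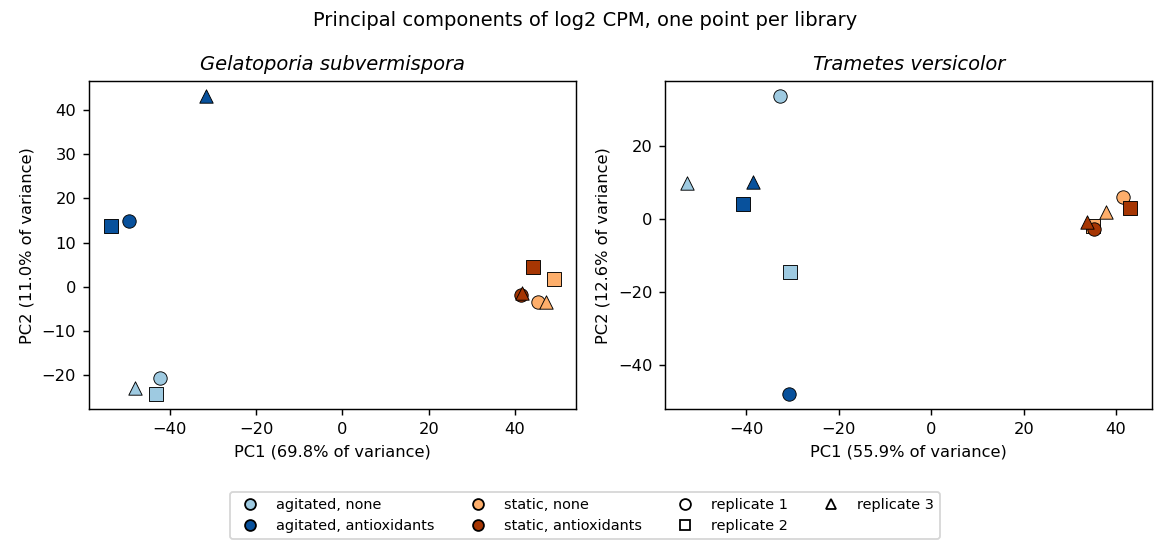
Principal components of log2 CPM, with 1 point per library, colour for the group and marker shape for the replicate number. The axes give PC1 and PC2 with their percent of variance, and static and agitated libraries lie on opposite sides of PC1 in both species, at 69.8% and 55.9% of the variance.

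The first comparison asked how gene expression in static G. subvermispora cultures differed from that in agitated cultures. Close to as many genes were higher in static culture as were lower, 2499 against 2584 of the 10529 tested. The rises were larger: 374 genes rose and 176 fell by 4-fold or more, and 67 rose and 23 fell by 16-fold or more. The genes that rose by at least 2-fold, 1008 in all, went from 1.76% ± 0.158 (SD, n = 3) of gene reads in agitated cultures to 9.57% ± 1.52 in static ones. The 739 genes that fell by at least 2-fold went from 18.5% ± 0.733 to 5.33% ± 0.34. Among the 200 most abundant genes, 27 rose and 87 fell. gene11533 showed the largest rise, from 1.09 ± 0.253 CPM to 450 ± 268 CPM (log2 fold change 8.67, SE 0.59, edgeR adjusted p = 1.1e-06), and gene7069 rose from 10.5 ± 5.18 to 1790 ± 1160 CPM (log2 fold change 7.40, SE 0.88, edgeR adjusted p = 5.1e-05), with a log2 fold change of 6.81 without static replicate 3. gene10815, among the abundant transcripts of agitated cultures at 2410 ± 246 CPM, fell to 32.7 ± 11.1 CPM (log2 fold change -6.19, SE 0.49, edgeR adjusted p = 3.2e-06). gene3220 fell from 197 ± 28.4 to 3.87 ± 0.36 CPM (log2 fold change -5.66, SE 0.47, edgeR adjusted p = 4.3e-06). The calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the groups did not overlap for 62.2% of the tested genes, where chance gives 10%. The balance of rises and falls depended on the scaling: with library totals alone, which moved the median gene by 0.182 on the log2 scale, 67.7% of the called genes were higher in static culture instead of 49.2%.

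With antioxidants present in both, static and agitated G. subvermispora cultures again differed in about as many genes, 2471 higher and 2804 lower in static culture. Of these, 1614 were also called higher without antioxidants, where independent lists of those sizes would share 586.5, and 1786 were called lower in both, against 688.2 for independent lists. The genes higher in both had a median of 9.27 CPM in agitated and 24.4 CPM in static cultures without antioxidants, and 9.14 and 22.2 CPM with them. Those lower in both went from a median of 53.6 to 28.4 CPM without and from 52.5 to 29.3 CPM with antioxidants. A core of 206 genes rose and 101 fell by 4-fold or more in both states. Opposite calls were few, with 54 genes higher without and lower with antioxidants and 43 the other way. Across the 10529 genes the log2 fold changes of the 2 comparisons, which share no library, correlated with Pearson's r = 0.822 and Spearman's rho = 0.748, although genes are not independent replicates. gene11533 was again among the largest rises (log2 fold change 7.60, SE 0.58), next to gene11534, which went from 2.54 ± 1.28 to 593 ± 159 CPM (log2 fold change 7.89, SE 0.60). Both had an edgeR adjusted p of 2.5e-06. gene10815 fell again (log2 fold change -7.42, SE 0.52, edgeR adjusted p = 1.6e-06), as did gene6409 (log2 fold change -6.49, SE 0.48, edgeR adjusted p = 2e-06). With library totals alone the median gene moved by 0.22 on the log2 scale, and 71.4% of the called genes were higher in static culture instead of 46.8%.

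**Figure D2:**
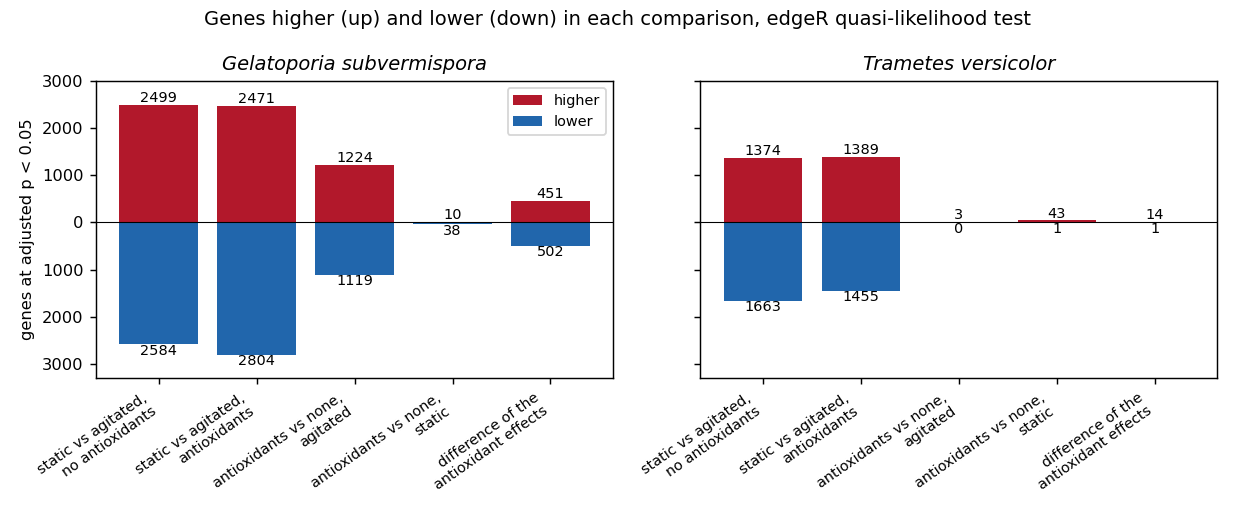
Number of genes at adjusted p under 0.05 in edgeR's quasi-likelihood test, for each of 5 comparisons in each species, with genes that were higher drawn upward in red and genes that were lower drawn downward in blue. The bars for static against agitated cultures are the tallest in both species, and the antioxidant comparison in agitated cultures gives 1224 higher and 1119 lower genes in G. subvermispora and 3 higher genes in T. versicolor.

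The next comparison asked what the antioxidants changed in agitated G. subvermispora. They raised 1224 genes and lowered 1119, 22.3% of those tested, mostly by modest amounts, since the median absolute log2 fold change of the called genes was 0.56. The raised genes had a median of 42.6 CPM without and 62.9 CPM with antioxidants, and the lowered genes 53.2 and 32.8 CPM. By 2-fold or more, 214 genes rose and 216 fell. The fall of gene3220 was the largest among the better-counted genes, from 197 ± 28.4 to 8.72 ± 5.11 CPM (log2 fold change -4.51, SE 0.43, edgeR adjusted p = 7.7e-05), and it was also lower in static than in agitated cultures, a comparison that uses the same 3 agitated libraries. gene5500 fell from 275 ± 15.9 to 29.8 ± 6.25 CPM (log2 fold change -3.21, SE 0.27, edgeR adjusted p = 3.5e-05) and stood at 224 ± 51.4 CPM in static cultures without antioxidants. gene6890 rose from 8.07 ± 5.41 to 93.2 ± 95.9 CPM (log2 fold change 3.51, SE 0.68, edgeR adjusted p = 0.0043), against 94.0 ± 13 CPM in static cultures without antioxidants. gene8710 rose from 2.72 ± 1.28 to 21.9 ± 22 CPM (log2 fold change 2.98, SE 0.62, edgeR adjusted p = 0.0066). Both rises were unevenly shared by the antioxidant replicates. gene6890 stood at 46.5, 29.7 and 203.6 CPM in replicates 1, 2 and 3, and without replicate 3 its log2 fold change was 2.20 (edgeR adjusted p = 0.0069), against 4.23 without replicate 1 of the cultures without antioxidants, and that of gene8710 was 1.72 (edgeR adjusted p = 0.0021). The count was 2565 without antioxidant replicate 3, the library that stood apart, and it fell to 1438 and 1436 without replicate 1 or replicate 3 of the cultures without antioxidants. With library totals alone, 39.2% of the called genes were raised, against 52.2%.

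In static G. subvermispora the same antioxidants changed 48 genes, of which 38 fell and 10 rose. The 38 lowered genes had a median of 95.5 CPM in static cultures without antioxidants and 40.1 CPM with them, and 18 of them fell by 2-fold or more. Of the 38, 21 were also called higher in static than in agitated cultures without antioxidants, a comparison that uses the same 3 static libraries. The largest falls were those of gene4018, from 69.9 ± 49.4 to 1.45 ± 0.261 CPM (log2 fold change -5.63, SE 0.82, edgeR adjusted p = 0.016), and gene7418, from 977 ± 413 to 95.8 ± 21.9 CPM (log2 fold change -3.35, SE 0.56, edgeR adjusted p = 0.031). gene3192 rose from 107 ± 9.68 to 194 ± 25.5 CPM (log2 fold change 0.85, SE 0.13, edgeR adjusted p = 0.018), and gene752 rose from 33.7 ± 0.408 to 60.2 ± 10.3 CPM (log2 fold change 0.84, SE 0.10, edgeR adjusted p = 0.0058). The count was small and unstable, at 175 genes without static replicate 1 of the cultures without antioxidants. That library was the shallowest, and it correlated best with a static antioxidant library. The count was between 10 and 27 without any other static library, while DESeq2 called 248. Same-number static libraries correlated, possibly by coincidence. With the number as a block, edgeR called 28 genes, 24 of them falls, and 25 of the 28 were among the 48. With the block in the static libraries only, a choice made after seeing the data, it called 90, among them 46 of the 48. The fall of gene7418 had an edgeR adjusted p of 0.0516 with the first block and 0.0376 with the second, and that of gene4018 an adjusted p of 0.102 in limma-voom. The calls of gene4018 and gene7418 were lost without any of the 5 other static libraries (edgeR adjusted p up to 0.114 and 0.169), that of gene3192 without replicate 2 or 3 of either static group (edgeR adjusted p up to 0.0887), and upper-quartile scaling put 32% of the called genes among the rises, against 20.8%.

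Whether the antioxidant effect in G. subvermispora depended on agitation was tested directly, as the difference between the 2 effects. It differed for 953 genes, with a more positive effect in static culture for 451 and a more negative one for 502. For 850 of the 953 the effect was larger in agitated culture, and 848 were called there against 32 in static culture. The 451 genes went from a median of 75 to 39.1 CPM with antioxidants in agitated culture and from 50.9 to 53.5 CPM in static culture. The 502 genes went from 46.2 to 74 CPM in agitated and from 59.2 to 51.3 CPM in static culture. gene3220 headed the first group with a difference of 5.18 (log2, SE 0.62, edgeR adjusted p = 0.0011), and gene522 followed with 3.97 (SE 0.78, edgeR adjusted p = 0.012), or 3.10 (edgeR adjusted p = 0.016) without static antioxidant replicate 3, which stood at 455 CPM against 137 and 123 CPM in replicates 1 and 2. In the second group gene6277 differed by -4.41 (SE 0.64, edgeR adjusted p = 0.0031), rising from 117 ± 4.82 to 782 ± 524 CPM in agitated culture and standing at 93.0 ± 21 without and 29.4 ± 3.19 CPM with antioxidants in static culture. gene3464 differed by -4.19 (SE 0.87, edgeR adjusted p = 0.016). Across the 10529 genes the correlation of the antioxidant effects in the 2 culture states was near 0 (Pearson's r = 0.019, Spearman's rho = 0.04). Genes called in both states went the same way about as often as opposite ways: 11 were lowered and 3 raised in both, where independent lists would share 4 and 1.2, while 9 were raised in agitated and lowered in static culture and 4 the other way, against 4.4 and 1.1. Of the genes raised and lowered in agitated culture, 57.4% and 56.4% had the same sign in static culture. The number of genes was 1496 without agitated antioxidant replicate 3 and 1516 with DESeq2. In 2 settings added after seeing the data it was 2664 (limma-voom with library quality weights) and 629 (thinned to the T. versicolor totals). The number was 504, 522 and 459 without replicate 1, 2 or 3 of the agitated cultures without antioxidants, 482 and 589 without replicate 2 or 3 of the static cultures without antioxidants, and 541 and 617 without static antioxidant replicate 1 or 3.

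**Figure D3:**
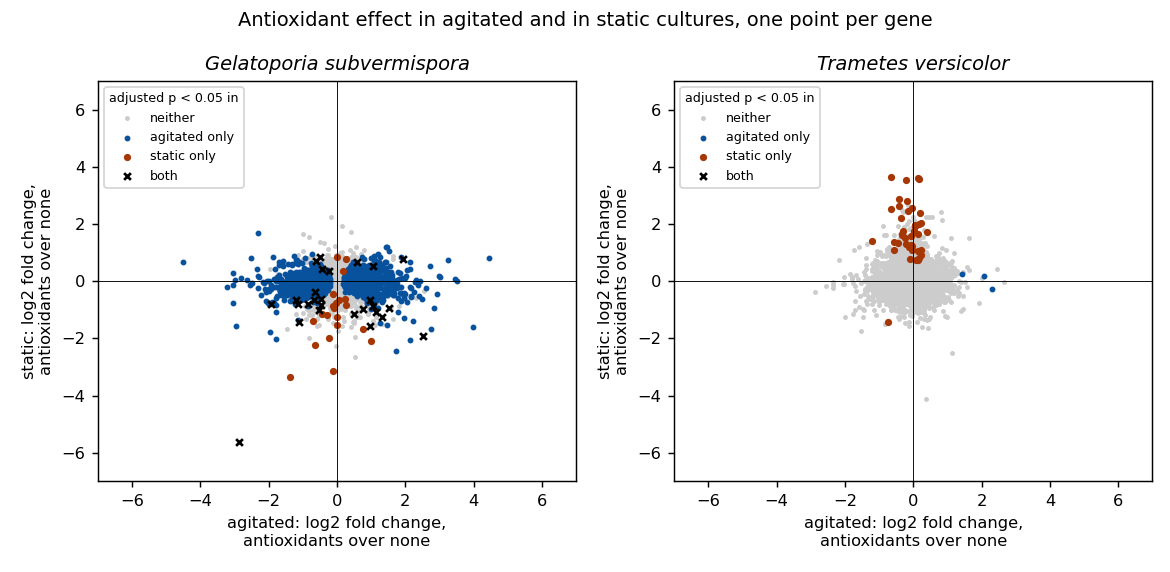
Log2 fold change with antioxidants over none in agitated cultures (horizontal axis) and in static cultures (vertical axis), with 1 point per tested gene and colour for the culture state in which the gene reached adjusted p under 0.05. In G. subvermispora the called genes spread along the horizontal axis (2343 in agitated, 48 in static culture), and in T. versicolor they spread along the vertical axis (3 in agitated, 44 in static culture).

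In T. versicolor, static culture lowered more genes than it raised, 1663 against 1374 of the 10505 tested. The imbalance was larger among strong changes, with 284 genes down and 72 up by 4-fold or more and 41 down and 4 up by 16-fold or more. The 820 genes that fell by at least 2-fold went from 11.6% ± 1.71 of gene reads in agitated cultures to 3.21% ± 0.161 in static ones, and the 492 that rose by at least 2-fold went from 1.43% ± 0.214 to 4.34% ± 0.362. Of the 200 most abundant genes, 15 rose and 39 fell. gene10802 had the largest rise, from 1.87 ± 0.84 to 383 ± 140 CPM (log2 fold change 7.67, SE 0.43, edgeR adjusted p = 9.8e-07), followed by gene11627, from 3.02 ± 1.41 to 105 ± 56.1 CPM (log2 fold change 5.13, SE 0.54, edgeR adjusted p = 0.00015). gene1249 fell from 268 ± 193 to 2.68 ± 0.533 CPM (log2 fold change -6.61, SE 1.31, edgeR adjusted p = 0.0059). gene4099 fell from 147 ± 174 to 2.04 ± 0.724 CPM (log2 fold change -6.19, SE 1.69, edgeR adjusted p = 0.024), and its log2 fold change was -4.62 without agitated replicate 3. Its call was lost without that library or any of the 3 static libraries (edgeR adjusted p up to 0.0824), in limma-voom (adjusted p = 0.203, or 0.106 with library quality weights, added after seeing the data) and with only the 2 groups in the fit (edgeR adjusted p = 0.0847). The count was 1987 without static replicate 1, and with library totals alone, which moved the median gene by 0.113 on the log2 scale, 59.1% of the called genes were higher in static culture instead of 45.2%.

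With antioxidants in both, static T. versicolor cultures had 1389 genes higher and 1455 lower than agitated ones. Of these, 895 were higher and 1046 lower in both antioxidant states, where independent lists would share 181.7 and 230.3, and 14 were lower without and higher with antioxidants. The 895 genes had a median of 18.9 CPM in agitated and 38.9 CPM in static culture without antioxidants, and the 1046 genes 52.5 and 21.7 CPM. A core of 45 genes rose and 155 fell by 4-fold or more in both states, and the fallen core went from a median of 50.9 to 5.06 CPM without and from 40 to 4.35 CPM with antioxidants. The log2 fold changes of the 2 comparisons correlated across genes with Pearson's r = 0.833 and Spearman's rho = 0.79. gene10802 again rose most (log2 fold change 7.16, SE 0.43, edgeR adjusted p = 1.7e-06), and gene5912 rose from 2.24 ± 0.222 to 70.6 ± 28.7 CPM (log2 fold change 4.97, SE 0.67, edgeR adjusted p = 0.00085). gene4099 (log2 fold change -6.27, SE 1.69, edgeR adjusted p = 0.025) and gene1249 (log2 fold change -6.15, SE 1.37, edgeR adjusted p = 0.011) fell most again, and both calls were lost in limma-voom (adjusted p = 0.129 and 0.0814). The call of gene4099 was also lost with the quality weights (limma-voom adjusted p = 0.066) and without agitated antioxidant replicate 1 or any static antioxidant library (edgeR adjusted p up to 0.0866). Its log2 fold change was -5.25 without agitated antioxidant replicate 1, that of gene1249 was -6.80 without static antioxidant replicate 3, and the count was 1675 without static antioxidant replicate 2.

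In agitated T. versicolor the antioxidants raised 3 genes in edgeR's test. gene3318 rose from 147 ± 46.9 to 621 ± 171 CPM (log2 fold change 2.07, SE 0.28, edgeR adjusted p = 0.013), against 198 ± 50.3 CPM in static cultures without antioxidants. gene9939 rose from 34.6 ± 4.89 to 92.4 ± 6.24 CPM (log2 fold change 1.41, SE 0.16, edgeR adjusted p = 0.0064), near its level of 105 ± 20.1 CPM in static cultures without antioxidants. The third, gene7615, lies below the abundance required of named genes and was chosen after its values were seen. It rose from 3.83 ± 1.19 to 19.2 ± 6.29 CPM (log2 fold change 2.32, SE 0.31, edgeR adjusted p = 0.013). No gene was called lower by edgeR. In that test 684 of 10505 genes in either direction had an unadjusted p under 0.05, where chance alone gives a share of 0.05. The groups did not overlap for 8.7% of the tested genes, where chance gives 10%. Limma-voom called 2 rises and 0 falls and DESeq2 called 14 rises and 11 falls. The count ranged from 0, without agitated replicate 3 of the cultures without antioxidants, to 35 (10 raised and 25 lowered), without replicate 2 of the same group, with 17 (3 raised and 14 lowered) without its replicate 1, 6, all raised, without antioxidant replicate 1 and 1 without antioxidant replicate 2 or 3. The calls of gene3318 and gene7615 were lost without agitated replicate 3 of the cultures without antioxidants or antioxidant replicate 2 or 3 (edgeR adjusted p up to 0.077 and 0.113), that of gene9939 without the first of these (edgeR adjusted p = 0.0623), and that of gene7615 in limma-voom (adjusted p = 0.0685). The count was 42 (12 raised and 30 lowered) without both agitated replicate 1 libraries, which stood apart, a choice made after seeing the data, and 0 when only the 6 agitated libraries entered the fit.

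In static T. versicolor the antioxidants raised 43 genes and lowered 1. The raised genes had a median of 14.9 CPM in static cultures without antioxidants and 50.0 CPM with them, and 38 of the 43 rose by 2-fold or more. Their medians in agitated cultures were 27.2 CPM without and 21.3 CPM with antioxidants, and 22 of the 43 were called lower in static than in agitated cultures without antioxidants, a comparison that shares the 3 static libraries. gene7591 rose from 15.5 ± 1.41 to 185 ± 10.6 CPM (log2 fold change 3.57, SE 0.37, edgeR adjusted p = 0.00094), and gene4441 from 2.15 ± 0.386 to 25.8 ± 5 CPM (log2 fold change 3.53, SE 0.37, edgeR adjusted p = 0.00048). The single lowered gene, gene13672, went from 27.2 ± 2.62 to 10.1 ± 1.07 CPM (log2 fold change -1.42, SE 0.27, edgeR adjusted p = 0.037), and its call was lost on leaving out any 1 of the 6 static libraries (edgeR adjusted p 0.106 to 0.234) and in limma-voom (adjusted p = 0.146). The 3 static antioxidant libraries differed from those without in another way: their 6 most abundant genes took 24.8% ± 1.82 of the gene reads against 17.9% ± 4.58, and 21.4% ± 0.793 of all their reads were not aligned against 17.1% ± 2.19. The count was 12 to 23 without any 1 of the static libraries other than antioxidant replicate 3, where it was 32, and it was 99 with DESeq2 and 145 with only the 6 static libraries in the fit.

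The antioxidant effect differed between static and agitated T. versicolor for 15 genes, 14 of them with the more positive effect in static culture. These 14 genes had medians of 18 and 17.1 CPM in agitated cultures without and with antioxidants, and of 13.8 and 52.3 CPM in static cultures. All 14 were called higher with antioxidants in static culture. gene4441 differed by 3.74 (log2, SE 0.49, edgeR adjusted p = 0.0053) and gene7591 by 3.40 (SE 0.50, edgeR adjusted p = 0.025). The single gene with the opposite sign was gene7615, at -2.59 (SE 0.46, edgeR adjusted p = 0.044), which rose in agitated culture and stood at 6.44 ± 1.92 and 5.34 ± 1 CPM in static culture without and with antioxidants. Across the 10505 genes the 2 antioxidant effects correlated at Pearson's r = 0.038 and Spearman's rho = 0.059, which says little here, because over all genes no effect in agitated culture was measurable above the replicate spread. The difference for gene7591 was 2.66 (edgeR adjusted p = 0.00029) without agitated replicate 2 of the cultures without antioxidants. Its call was lost without any 1 of the static or agitated antioxidant libraries (edgeR adjusted p up to 0.123) and that of gene7615 without any library but agitated replicate 2 without antioxidants and agitated antioxidant replicate 1 (edgeR adjusted p up to 0.19), and also in limma-voom (adjusted p = 0.145), with upper-quartile scaling and with the filter of 10 CPM (edgeR adjusted p = 0.0524 and 0.0566). The count was 8 without static replicate 3 of the cultures without antioxidants, 64 with DESeq2 and 55 without both agitated replicate 1 libraries.

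**Figure D4:**
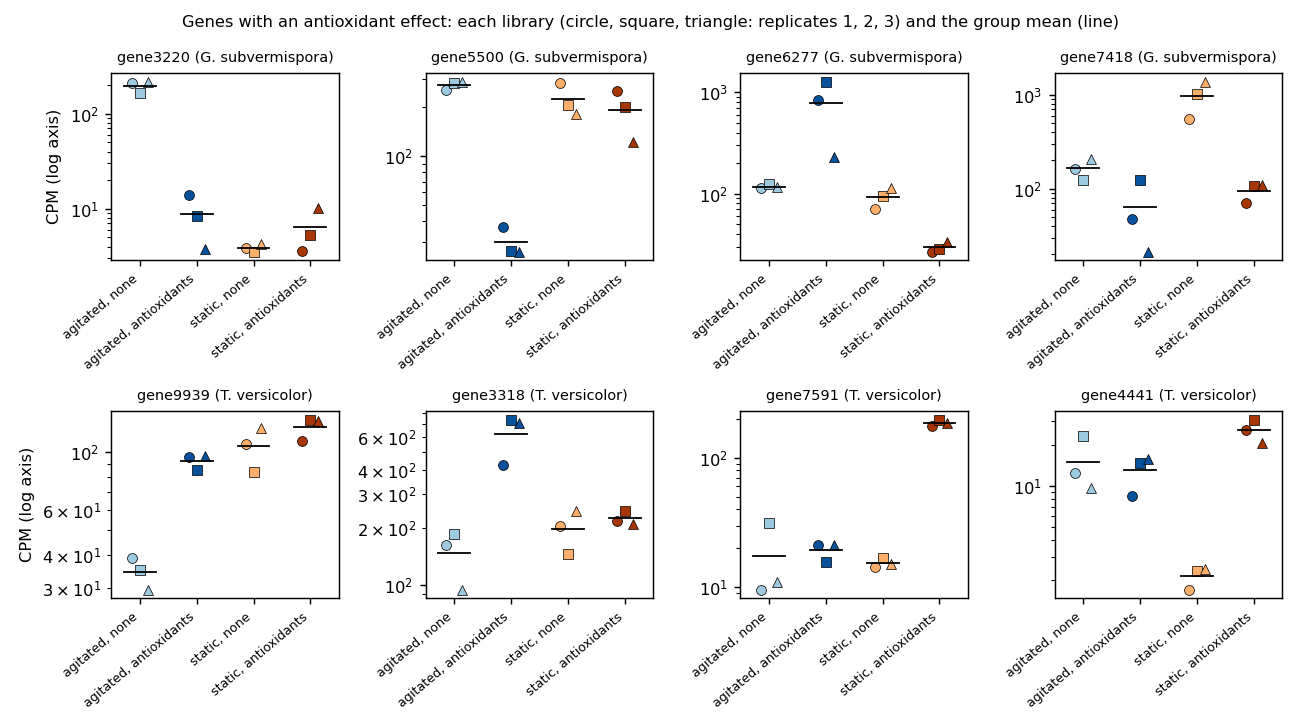
CPM on a log axis in each of the 4 groups for 4 genes of G. subvermispora and 4 of T. versicolor with an antioxidant effect, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. gene3220 stands at 197 CPM in agitated cultures without antioxidants and at 3.87 to 8.72 CPM in the other 3 groups, and gene7591 stands at 185 CPM in static cultures with antioxidants and at 15.5 to 19.4 CPM elsewhere.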

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

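Tests for exchanged sample labels, the thinning of libraries to lower depths, the fits without both agitated replicate 1 libraries, the differences within replicate numbers and the regroupings with one culture state held were chosen only after the results were seen. The antioxidant effect differed between static and agitated culture for 953 genes in G. subvermispora and 15 in T. versicolor, by edgeR's test of the difference itself. The named genes with such a difference (log2, static minus agitated) were gene3220 (5.18), gene522 (3.97), gene6277 (-4.41) and gene3464 (-4.19) in G. subvermispora and gene4441 (3.74), gene7591 (3.40) and gene7615 (-2.59) in T. versicolor. Reads outside the gene counts also differed. In static G. subvermispora, 5.31% of the reads of antioxidant libraries fell outside genes against 5.13% without antioxidants, and every antioxidant library lay above every other. In static T. versicolor, 21.42% were not aligned against 17.09%, and 14.84% fell outside genes against 12.95%, again with no overlap. With 3 libraries against 3 the exact two-sided permutation p of each is 0.1, the smallest it can give (adjusted p = 0.53 over 16 tests).

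Antioxidants changed 2343 genes in agitated G. subvermispora and 3 in agitated T. versicolor. The lower depth of the T. versicolor libraries does not by itself account for the gap, since 1746 G. subvermispora genes were still called after thinning to the T. versicolor totals. A wider replicate spread in T. versicolor was tested through the covariance of effects estimated from separate libraries, which noise does not inflate: it gave an effect SD of 0.411 (log2, 0.369 to 0.454 over 18 pairs) in G. subvermispora, while in T. versicolor the mean covariance was below 0 (signed root -0.144, range -0.387 to 0.23). The T. versicolor range lay below that of G. subvermispora. A variance of effects cannot be below 0, however, so this test does not exclude replicate spread as an explanation. The replicate SD (log2) was 0.385 in agitated T. versicolor and 0.238 in agitated G. subvermispora. Thinning kept the G. subvermispora spread, so lower depth and wider spread together were not tested. The T. versicolor count rose to 42 without both agitated replicate 1 libraries. Species, culture age and genome differ together here, and a biological difference between the species remains open as an untested hypothesis.

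In G. subvermispora the antioxidants changed 2343 genes in agitated and 48 in static cultures. The gap was narrower in DESeq2, with 2787 and 248 genes. It was narrower too in limma-voom with library quality weights, added after seeing the data, with 4191 and 756. Thinning all libraries to the lowest total, that of a static library, left 1885 genes in agitated culture and 35 in static culture, and without agitated antioxidant replicate 3 the agitated count was 2565, which argues against depth and against that library as the cause. The noise-free effect SD in static cultures was 0.188 (range -0.089 to 0.284), below the whole range in agitated cultures. Its lower end is below 0, which no variance of effects can be. Differences within replicate numbers, which pairing does not bias, gave 0.21 (0.179 to 0.252), against 0.411 (0.391 to 0.44) in agitated cultures. The bound for this second measure was written after the results were seen, and the measure missed the bound fixed in advance. In both measures the static values lay below the agitated ones, which argues against replicate spread as the whole cause of the gap. Exchanged static labels would need a regrouping of the 6 static libraries with far more genes, and the largest number for any of the 10 was 98. A response to antioxidants that is weaker in static culture may be biological, as a hypothesis found and tested on the same data.

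Agitated antioxidant replicate 3 of G. subvermispora differed at least 2-fold from the mean of replicates 1 and 2 in 453 of 7703 well-counted genes. Of the 93 genes higher in it, 64.5% were at least 2-fold higher in static than in agitated cultures, against 5.3% of all, while of the 360 genes lower in it 22.5% were at least 2-fold lower in static cultures, against 7% of all. RNA from a static culture mixed into it would raise all static-specific genes alike, yet 41.2% of 34 genes at least 16-fold higher in static culture stood at a level that implies no static RNA (median implied share 0.19%). Its highest correlation with a library of another group was 0.967, below the 0.972 to 0.975 with its own group, which argues against exchanged labels. What set this library apart stays open, and no biological explanation was tested.

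Other groupings of the same libraries were tried for each count. For the difference between antioxidant effects in G. subvermispora, 3 of 100 splits drawn gave at least as many genes as the real 953, the real one included, and the highest other gave 1173. All 3 were among the 7 that kept the real agitated groups, and splits that kept neither state's groups gave at most 0. In T. versicolor, 5 of 100 splits reached the real 15, the highest other 29, and all 5 were among the 8 that kept the real static groups. These splits therefore show the effect within 1 culture state and do not test the difference itself. With the agitated groups of G. subvermispora held and the static libraries assigned in all 20 ways, 6 gave at least 953 genes, the real one included, and the highest other 1397. With the static groups of T. versicolor held, 12 of 20 assignments of the agitated libraries gave at least 15, the highest other 42. In both cases the number of genes mostly followed the state with the larger antioxidant effect. The 6 libraries of any other comparison allow 10 splits, too few for a share under 0.05. For static against agitated culture without and with antioxidants, the real counts of 5083 and 5275 in G. subvermispora compare with at most 0 and 1 in any other split, and 3037 and 2844 in T. versicolor with none in any other split. For antioxidants in agitated culture, 2343 compares with 0 in G. subvermispora and 3 with 1 in T. versicolor. For antioxidants in static culture, 44 compares with 0 in T. versicolor. In static G. subvermispora, where same-number libraries correlated, the real 48 compares with at most 0 in the 3 other splits that part all 3 same-number pairs. Among the remaining 6, which part 1 pair, 1 gave 98, so that 2 of the 10 splits reached 48. It grouped replicate 1 without antioxidants with antioxidant replicates 1 and 2, which keeps pairs 1 and 3 whole on opposite sides. Whether the numbers mark true pairs is not known, so this split still counts against the 48.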

How the results depend on the processing

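Limma-voom with library quality weights, the thinned libraries, the block in static libraries only and the fits without both agitated replicate 1 libraries or the 6 most abundant genes were chosen after seeing the data. Comparisons are listed in the order static against agitated without and with antioxidants, antioxidants in agitated and in static culture, and the difference between the antioxidant effects. The low-count filters, all scalings and limma-voom kept every count of called genes within 1.5 times, as did leaving out the 6 most abundant genes, run in T. versicolor only. A minimum absolute log2 fold change of 1 left 1747, 1674, 430, 18 and 368 genes in G. subvermispora and 1312 and 1246 for the first 2 in T. versicolor, fewer by construction. DESeq2 called 248 genes for antioxidants in static culture and 1516 for the difference in G. subvermispora, and 25, 99 and 64 for the last 3 comparisons in T. versicolor. Quality weights gave 4191, 756 and 2664 for the last 3 in G. subvermispora and 4548, 7, 138 and 38 for the last 4 in T. versicolor. With only the 2 groups compared, the counts were 82 for static G. subvermispora and 0 and 145 for antioxidants in agitated and static T. versicolor. Without both agitated replicate 1 libraries, T. versicolor gave 42, 116 and 55 for the last 3. Thinned to the T. versicolor totals, G. subvermispora gave 629 for the difference. For these shifts other than the first, the cause was not tested. Leaving out 1 library at a time gave ranges of 4253 to 4920, 4420 to 5809, 1436 to 2565, 10 to 175 and 459 to 1496 in G. subvermispora and 1987 to 2838, 1675 to 2853, 0 to 35, 12 to 32 and 8 to 19 in T. versicolor. Only in static G. subvermispora did all 3 same-number pairs correlate above 0.1, which may be a coincidence. Over all groups, 4 of 12 libraries of G. subvermispora and 1 of 12 of T. versicolor correlated best with their own number. With the replicate block, the counts were 28 for antioxidants in static G. subvermispora and 1 for agitated T. versicolor, and the other 8 stayed within 1.5 times. In T. versicolor, where libraries share only a number, the block put the edgeR adjusted p over 0.05 for gene4099 in static against agitated culture without and with antioxidants (0.0634 and 0.0561), for gene3318 and gene7615 in agitated culture (0.0907 each), and for gene7591 and gene7615 in the difference (0.0562 and 0.11). In static G. subvermispora the block ended the call of gene7418 and of no other named gene. With the block in the static libraries only, that count was 90. The correlation across genes of the static effect with and without antioxidants stayed between 0.797 and 0.838 in G. subvermispora and 0.791 and 0.841 in T. versicolor on leaving out a library, and that of the antioxidant effects between -0.026 and 0.062 and between -0.012 and 0.078. Over the named genes, 400 of the values under other settings and 210 of those with a library left out kept their direction and call, 24 and 54 kept the direction and lost the call, and none reversed. The minimum fold change used the main fit again, so its values among the 400 were fixed in advance. The named genes were picked as the largest called effects, which makes a reversal unlikely from the start. DESeq2 gave no adjusted p for gene7615 in the agitated comparison. The set tests on gene lists were not run. At the depth and replicate spread of T. versicolor together, simulated 2-fold differences between antioxidant effects were found for 22 of 100 genes picked above a minimum mean CPM. Each simulated gene had the same spread in all groups.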

Other observations

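Some genes that antioxidants moved in agitated G. subvermispora also differed between static and agitated cultures. Whether the 2 effects share an axis was examined over all genes, by a test written before its result was seen, and the values per library were added after it. The 1224 genes raised by antioxidants in agitated culture held 445 that were higher in static than in agitated cultures without antioxidants, where independent lists would share 290.5, and 204 that were lower, against 300.4. The 1119 lowered genes held 523 that were lower in static culture, against 274.6, and 213 that were higher, against 265.6. Both comparisons use the same 3 agitated libraries, which alone raises such overlaps. In 100 simulations of unchanged groups against those libraries the covariance of the 2 effects averaged 0.0151 and reached at most 0.0165, while the observed value over 7703 genes was 0.0745, higher by 0.0594. The excess came mainly from agitated antioxidant replicate 3. Taken alone, the covariance was 0.1674 for replicate 3, 0.0435 for replicate 1 and 0.0126 for replicate 2, where the simulations reached at most 0.0176, 0.0168 and 0.0169. Without replicate 3 the excess was 0.013. Without it, 453 raised genes were higher and 379 lower in static culture, against 375.3 and 389.9 for independent lists, and 537 lowered genes were lower and 288 higher, against 338 and 325.3. On the first principal component, replicate 3 lay at -31.71, nearer the static libraries than the cultures without antioxidants (-48.18 to -42.41), and replicates 1 and 2 lay farther away (-49.54 and -53.68). A movement of agitated cultures toward the static state therefore cannot be told apart from the deviation of 1 library. The correlation of the 2 effects was 0.19 and 58% of genes had the same sign, against averages of 0.494 and 66.4% (65 to 67.6%) in the simulations. These 2 values decide nothing, because real effects that are not shared lower both. With 3 shared libraries no split into separate controls of at least 2 libraries was possible.

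Gene numbers carried information in themselves. The order of the numbers was tested as a proxy for genome order, and the test on genes 3 to 5 numbers apart was chosen after the result was seen. Genes with neighbouring numbers changed together in static against agitated culture without antioxidants: the mean Spearman correlation of log2 fold changes 2 to 5 numbers apart was 0.093 in G. subvermispora and 0.045 in T. versicolor, above the highest of 1000 shuffles, 0.018 in each. Directly adjacent numbers correlated at 0.221 and 0.17. Reads shared by overlapping genes could raise the value for direct neighbours, and no coordinates were used. The correlation 3 to 5 numbers apart was 0.389 of that value in G. subvermispora and 0.259 in T. versicolor. Both ratios lie between the bounds set for either answer, so this cannot be told apart here. Shared reads do not account for the correlation 3 to 5 numbers apart, which was 0.086 in G. subvermispora and 0.044 in T. versicolor, above the highest of 1000 shuffles at the same distances, 0.019 in each. At 2, 10 and 50 numbers apart the correlation was 0.117, 0.05 and 0.012 in G. subvermispora and 0.047, 0.046 and 0.025 in T. versicolor. Beyond direct neighbours it thus hardly faded up to 10 numbers apart in T. versicolor. A candidate explanation is that numbers follow the genome and that neighbouring genes respond alike, but the T. versicolor values beyond direct neighbours do not single out near genes.

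Runs of consecutive numbers were first taken in static against agitated culture without antioxidants. The longest run raised at least 2-fold in static G. subvermispora held 12 genes, gene6885 to gene6896, with log2 fold changes of 1.13 to 3.71. It was singled out after its values were seen. The longest run in 1000 shuffles of the called genes held 7. There were 44 runs of 3 or more, against a median of 7 and a maximum of 17 in the shuffles. Within the same stretch, gene6888 to gene6891 rose with antioxidants in agitated culture, by 1.89 to 3.51, and by 0.97 to 2.2 without agitated antioxidant replicate 3. The other genes of the stretch were not called there (edgeR adjusted p 0.15 to 0.87). Both comparisons use the same agitated libraries without antioxidants, which alone can raise such an overlap. The falls in static G. subvermispora made 23 runs of 3 or more, against a maximum of 9 in the shuffles, with a longest run of 5, which the shuffles also reached. In T. versicolor the falls made 15 such runs, against a maximum of 11. Their longest run held 5 genes, gene953 to gene957, with falls of 2.45 to 5.75 on the log2 scale, and the shuffles also reached 5. The rises made 2 such runs, within the maximum of 5 in the shuffles, and their longest, gene7981 to gene7985, held 5 genes against at most 4 in the shuffles. With antioxidants in both cultures, G. subvermispora made 32 rising and 15 falling runs, against maxima of 16 and 8. T. versicolor then made 2 rising and 12 falling runs, against maxima of 7 and 7. The longest rising runs held 6 genes, gene11580 to gene11585, in G. subvermispora and again gene7981 to gene7985 in T. versicolor. The shuffles also reached 6 and 5.

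Some of the most abundant transcripts had close numbers as well, again singled out after their values were seen. In T. versicolor gene14264 alone took 8% of the gene reads, gene14262 took 3.98% and gene14263 3.05%. gene14260 and gene14261 were also among the 6 most abundant genes, and gene14394, the fourth at 1.72%, lay apart. In G. subvermispora gene10792 took 3.74%, gene10787 1.8% and gene10788 0.96%, while the other 3 of its 6 most abundant genes, gene8128, gene896 and gene1721, had distant numbers. What these genes encode is not stated in the files.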
